A study of Homo sapiens with 6 samples.

How the data were processed

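The data are RNA-seq libraries from 6 cultures: LARP7 knockout and wild-type MEFs, and MDA-MB-231 and HCC1937 cells with siLARP7 or siNC. The labels name total RNA, an Illumina library kit and MEF passages as a range, and whether poly(A) RNA was selected or strand was counted is not given in the sources used here. Reads were handled with cutadapt, FastQC and STAR on GRCh37, per the submitters' processing notes, which give no versions. The MEF table lists mouse gene IDs, and its genome build is not given in the sources used here. The authors deposited an RPKM value per gene and library, per the file headers, and these are the values analysed. The authors also deposited a log2 change per gene from the GFOLD program at a setting of 0.01, per the file headers, which shrinks changes towards 0 and is quoted only as their value. The design foresaw read counts as well, but the files hold RPKM, so the rules for normalized values were used. Each table column was matched to its library by the cell type of the table and the column name.

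Depth was recovered from the RPKM values, since 1 read in a gene of known length is worth a fixed amount. In the human tables, all single-exon genes under 50 reads with an unchanged annotation (2600 to 3432 per library, 100%) gave whole read numbers within 0.01. In MEFs, where no annotated gene lengths were used here, depth comes from the values of short genes alone. The read number of Rn7sk rests on lengths of 331 and 328 bases. At these depths 1 read in 1 kb is worth 0.0187 to 0.0271 RPKM. For human genes, approximate reads from exon lengths in GENCODE release 29 gave exact 95% Clopper-Pearson intervals of the ratio, and a value of 0 was set to 3 counts for a fold. PCR copies are not independent molecules, so intervals and floors cover counting error only. The 47 pseudoautosomal entries repeated on Y were left out of each human table.

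Per gene, the log2 ratio of LARP7-depleted to control was taken on RPKM + 1. Genes at 1 RPKM or more in at least 1 library of a pair were tested by size and called at 2-fold or more. With a pseudocount of 1, a 2-fold difference in RPKM falls just short of the rule for most genes. The groups, the tests, 35 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names LARP7, RN7SK, CDK1, CCNB1, BRCA1, BRCA2 and BARD1 whatever their values, the 6 highest and 6 lowest called protein-coding genes of a comparison, up to 4 called members of each list that stands apart or has 3 or more called members, up to 5 genes called the same way or in opposite ways in the human lines or the same way in all 3 cell types, and mouse sex-linked genes. Some genes that the rule names are not reported here. All other genes were chosen after their values were seen: uncalled list members given as examples, genes shared by MEFs and a human line, genes shared at a smaller threshold, and called list members outside the rule, which are CDC25C, Hist2h3c1, Igfbp3, Mmp9, Cldn3, Hoxc12, Sox2, S100b and IL1A. In MEFs mRNA genes were told by a pattern of names that was set, and once narrowed, after the files were seen.

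A list stands apart where the percentile of its median among 10000 random lists, drawn within 20 bins of mean expression, is under 2.5 or above 97.5. Lists with fewer than 5 measured members have no percentile. Percentiles printed as 0 or 100 mean that no random list, or every one, lay below. Genes were matched between species by symbol. Trends of the log2 ratio on GC content, log2 length of the longest transcript and mean level were fitted with polynomials of degree 3 over protein-coding genes of the human lines, a step chosen after the data were seen. The mean log2 ratio of the fitted genes was added back, so a shift between libraries stayed in values with the trend removed. This trend was not removed in MEFs, for which no transcript sequences were used here, so list percentiles there went without that check. Of the human entries, 52526 were matched to GENCODE by ID, 4116 by symbol and 6879 not at all. Matching by symbol was added after the check of histone genes by ID alone had values for 20 of 38 members in HCC1937, too few to count, and with it 34 had one. By ID alone, the percentiles of the G2/M, homologous recombination and histone lists in that line with the trend removed were 0, 3.87 and 100, each on the same side of the limits as with symbols.

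The steps were tested on simulated data drawn from the control values and depths, in runs made after a first look at the real values. Genes to change were drawn from those at 5 RPKM or more in the control, so the shares called do not cover lower genes. Of genes changed 3-fold, 98% were called in the MEF simulation (13851 genes), 100% in that of MDA-MB-231 (17221 genes) and 100% in that of HCC1937 (15640 genes). Of genes changed 2-fold, 12%, 10% and 14% were called, and of genes changed 1.5-fold none. Unchanged genes were called 0, 12 and 7 times. Of 100 unchanged lists, 7, 2 and 3 stood apart, and all 20 lists lowered 1.5-fold were found in each. Those lists were lowered on the log2 ratios themselves, for genes at 5 RPKM or more. Against counting error alone they are bound to be found, so this does not measure how well such lists are found in the real libraries. The simulated draws held counting error only, with genes independent of each other and no difference between cultures. False calls and lists apart can therefore be more frequent in the real libraries. A planted linear GC trend, with a correlation of 0.97 in both human simulations, was reduced to -0.01 and 0.01. The fit removes such a trend by construction. The MEF simulation assumed gene lengths of 2000 bases. Alternatives were 2 other scalings (a median ratio of 1, and a mean of ratios trimmed by 30% on ratio and 5% on level), level minimums of none and 5 RPKM, a pseudocount of 0.1 and a 1.5-fold threshold. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.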

Results

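RNA abundance was measured by sequencing in 6 libraries, which pair a LARP7-depleted culture with its control in each of 3 cell types. LARP7 is an RNA-binding protein that holds the noncoding RNA 7SK in the particle that restrains the elongation kinase P-TEFb, and the series title presents it as a substrate of the ubiquitin ligase BRCA1 with a role in genome instability. Mouse embryonic fibroblasts (MEFs), primary cells taken from mid-gestation embryos, were either LARP7 knockout or wild-type. MDA-MB-231 and HCC1937 are established human breast cancer lines, and HCC1937 is known for its mutant BRCA1 gene. Both lines received an siRNA against LARP7 (siLARP7) or the siNC control at 10 ng/ml. Each of the 6 groups held 1 library, so no difference below has a replicate check and none was tested. The depth behind the values was 37.3 M reads in the knockout and 36.9 M in the wild-type MEF library, 53.3 M (siLARP7) and 49.6 M (siNC) in MDA-MB-231, and 50.6 M (siLARP7) and 49.3 M (siNC) in HCC1937. A gene is called at least 2-fold higher or lower by a size rule on the log2(RPKM + 1) scale, which understates the change of low genes. Gene lists are described by the percentile of their median among 10000 random lists of the same size and expression, which is a description of these libraries. Intervals are 95% intervals for human genes and cover counting error only.

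LARP7 RNA was lower in every depleted library. In MEFs, Larp7 was at 15.2 RPKM in the wild-type and 5.72 RPKM in the knockout library (log2 ratio -1.27), so that 37.6% of the control level was still read from the gene. In MDA-MB-231, LARP7 was at 8.65 RPKM with siNC and 4.51 RPKM with siLARP7 (log2 ratio -0.81), which is 52.2% of the control with an interval from 48.2 to 56.4%. In HCC1937 it was at 5.62 and 2.89 RPKM (log2 ratio -0.77, or -0.67 once the libraries are scaled to a median ratio of 1), which is 51.4% of the control with an interval from 46.5 to 56.8%. With a trend on GC content, length and level removed, the LARP7 log2 ratio was -0.66 in MDA-MB-231 and -0.48 in HCC1937, at percentiles 1.25 and 10.8 of protein-coding genes. The size rule called the gene in MEFs and not in the human lines. The authors' deposited table lists log2 changes of -1.23, -0.81 and -0.79 for the gene in MEFs, MDA-MB-231 and HCC1937.

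The level read for the RNA partner of LARP7 was also lower in the depleted libraries of MEFs and MDA-MB-231. Whether poly(A) RNA was selected is not given, so how fully these libraries captured 7SK is not known. Its reads need not follow its abundance. The 7SK gene Rn7sk was at 1.49 RPKM in wild-type MEFs, which is about 18 reads, and was listed at 0 in the knockout, at least 6.07-fold lower when 0 is set to a floor of 3 counts. In MDA-MB-231, RN7SK was at 13.52 RPKM with siNC and 8.16 RPKM with siLARP7, 60.3% of the control with an interval from 48.6 to 74.7%. In HCC1937 it was at 6.61 and 5.25 RPKM, where the interval of the ratio, 59.2 to 106%, includes no difference. Apart from LARP7 and 7SK, no measured member of the list for the particle and P-TEFb was called in MEFs. For example, Mepce, which caps 7SK, was at 15.1 and 14.4 RPKM, Cdk9 at 19.4 and 17.5 RPKM, and the P-TEFb inhibitor Hexim1 at 14.6 and 19.7 RPKM.

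**Figure D1:**
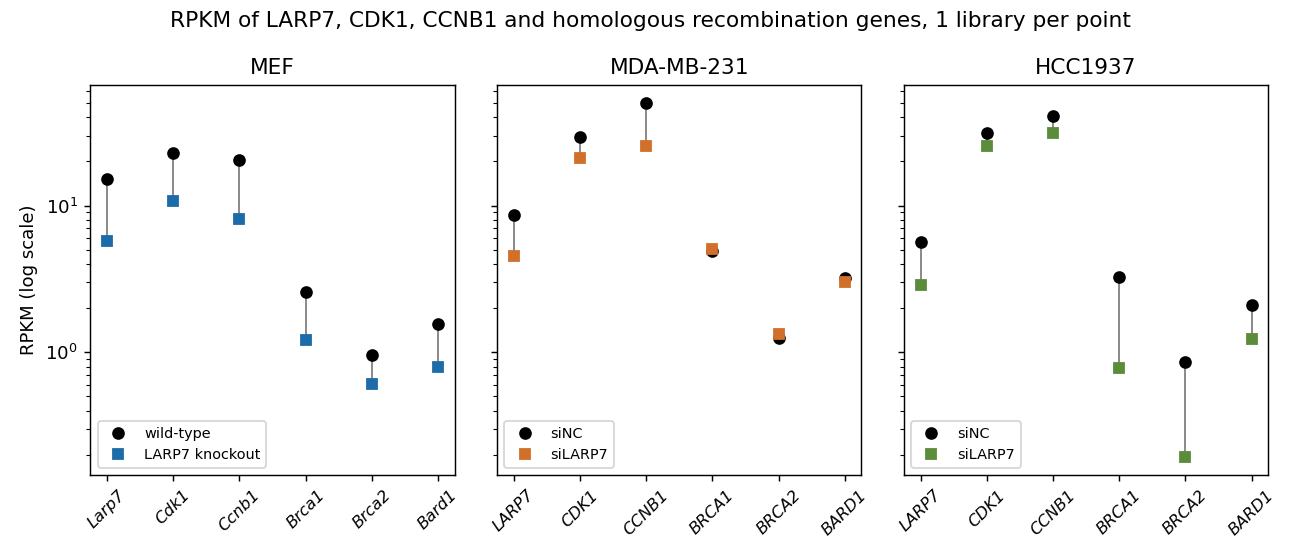
RPKM on a log scale of LARP7, CDK1, CCNB1 and 3 homologous recombination genes in the control library (circles) and the LARP7-depleted library (squares) of each cell type, with 1 library per point. BRCA1 was at 2.59 and 1.21 RPKM in MEFs, at 4.91 and 5.08 RPKM in MDA-MB-231 and at 3.29 and 0.785 RPKM in HCC1937.

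The knockout was compared with the wild-type MEFs to ask what loss of LARP7 does in untransformed cells. Genes for mitosis and DNA replication were lower in the knockout library, and interferon-stimulated genes, cytokines and replication-dependent histone genes were higher. Isg15, a ubiquitin-like antiviral modifier, stood at 5.70 RPKM in the wild-type and 82.6 RPKM in the knockout (log2 ratio 3.64). Plk1, a kinase that drives mitosis, stood at 41.9 and 14.6 RPKM (log2 ratio -1.46). Of 14479 genes tested, 348 were at least 2-fold higher and 128 at least 2-fold lower in the knockout. Among the 11077 with names of mRNA genes, 242 were higher and 72 lower.

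Genes of the CDK1 complex and the G2/M phases stood lowest among the lists. Of 32 measured members, 20 were at least 2-fold lower, none was higher, and the median log2 ratio was -1.07 (percentile 0). Cdk1, the mitotic kinase, was at 22.8 and 10.8 RPKM (log2 ratio -1.02), and its cyclin Ccnb1 at 20.5 and 8.17 RPKM (-1.23). Cdc20, which activates the anaphase-promoting complex, was at 79.6 and 30.5 RPKM (-1.36), the survivin gene Birc5 at 17.6 and 6.36 RPKM (-1.33), and the spindle motor Kif11 at 10.9 and 3.72 RPKM (-1.33). DNA replication and G1/S genes had a median of -0.66 (percentile 0), with 1 of 25 members called: Rrm2, a subunit of ribonucleotide reductase, at 107 and 52.6 RPKM (-1.01), which just missed the call once the libraries were scaled to a median ratio of 1 (-0.996).

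Genome maintenance lists were also low in the knockout library, with no single member called. The homologous recombination list had a median log2 ratio of -0.44 over 21 genes (percentile 0), without the check for a GC, length and level trend that was made in the human lines. Within it Brca1 was at 2.59 and 1.21 RPKM (log2 ratio -0.70) and its partner Bard1 at 1.57 and 0.8003 RPKM (-0.51). Brca2, at 0.954 and 0.609 RPKM, was below the level minimum. The checkpoint signalling list had a median of -0.33 (percentile 0.03), the Fanconi anemia pathway -0.25 (percentile 0.37) and the telomerase and shelterin list -0.30 (percentile 0.12). At a level minimum of 5 RPKM the Fanconi list had a median of -0.13, with too few members for a percentile. End joining genes, at -0.19 (percentile 4.99), did not stand apart.

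Interferon-stimulated genes stood highest, with 15 of 17 measured members at least 2-fold higher and a median log2 ratio of 1.73 (percentile 100), or 13 members with the trimmed mean scaling. After Isg15, the largest ratios were those of Bst2, which tethers budding virus particles, at 16.6 and 173 RPKM (3.31), and of the antiviral genes Ifit3, at 3.62 and 38.2 RPKM (3.09), and Ifit1, at 2.63 and 20.6 RPKM (2.57). Of NF-kB targets and cytokines, 11 of 19 were called higher, with a median of 1.22 (percentile 100). Il6, a proinflammatory cytokine, was at 11.3 and 41.6 RPKM (1.79), the adhesion molecule Icam1 at 4.44 and 18.1 RPKM (1.81), Il1a at 0.563 and 4.18 RPKM (1.73) and the chemokine Cxcl2 at 3.85 and 14.0 RPKM (1.62). Genes outside the lists went the same way: the acute-phase gene Saa3 was at 19.1 and 236 RPKM (3.56), the eotaxin gene Ccl11 at 0.526 and 11.9 RPKM (3.08), and Nos2, the inducible nitric oxide synthase, at 0.406 and 10.3 RPKM (3.0). Macrophage and leukocyte markers, of which 6 were measured, had a median of 0.45 (percentile 98.9) with none called, which dropped to 0.09 (percentile 74.9) without a level minimum and did not stand apart at a pseudocount of 0.1 (percentile 97.0), and Lyz2, the most abundant of them, was at 22.4 and 28.3 RPKM.

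The histone and matrix lists stood high too, with 34 members above 0 and 10 below in the first, and 14 and 5 in the second. The replication-dependent histone list had a median log2 ratio of 0.48 over 44 genes (percentile 100), with 5 called higher. These included Hist1h4h at 4.70 and 12.9 RPKM (1.29). The others, Hist2h2aa1 (1.31), Hist2h2aa2 (1.36), Hist2h3c2 (1.21) and Hist2h3c1 (1.01, or 0.96 and not called with the trimmed mean), lie in a cluster with near-identical copies that share reads, so their separate values are uncertain. Collagens and matrix genes had a median of 0.27 (percentile 99.9), with the proteoglycan genes Dcn, at 16.8 and 92.6 RPKM (2.40), and Lum, at 10.6 and 38.3 RPKM (1.76), as the called members. Hypoxia and glycolysis genes (median 0.31, percentile 99.9), p53 target genes (0.18, percentile 99.0) and mitochondrially encoded mRNAs (0.22, percentile 98.4) also stood high without a called member. Standing apart was common in MEFs, with 17 of 29 lists that had a percentile, against 4 of 27 in MDA-MB-231 and 9 of 27 in HCC1937. A small median that stands apart therefore sets a list off little in MEFs. The p53 target Cdkn1a, a CDK inhibitor, was at 259 and 339 RPKM.

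Genes of sterol metabolism and ribosomal protein genes were on the lower side. Cholesterol synthesis and uptake genes had a median of -0.48 (percentile 0), with the sterol carrier Stard4 called, at 15.9 and 5.67 RPKM (-1.34). Cytosolic ribosomal protein genes had a median of -0.20 over 82 genes (percentile 0), and La-related proteins, Larp7 among them, -0.27 (percentile 1.79). Among the lowest mRNA genes were Coch, a secreted protein of the inner ear, at 18.8 and 3.53 RPKM (-2.13), the homeobox gene Barx1 at 6.70 and 1.02 RPKM (-1.93), the erythroferrone gene Fam132b at 7.07 and 1.13 RPKM (-1.92), the CDK-associated phosphatase Cdkn3 at 7.19 and 1.63 RPKM (-1.64) and the tenascin gene Tnn at 9.62 and 2.64 RPKM (-1.55). The authors' deposited table lists 519 genes at a log2 change of at least 1 and 126 at -1 or less in this comparison. Both cultures carried Y-linked transcripts at close levels, with Ddx3y at 12.3 and 12.2 RPKM and Eif2s3y at 10.6 and 10.3 RPKM, and Xist was near 0 in both. Passage numbers of these primary cultures are given only as a range, so a passage difference between the libraries is open.

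**Figure D2:**
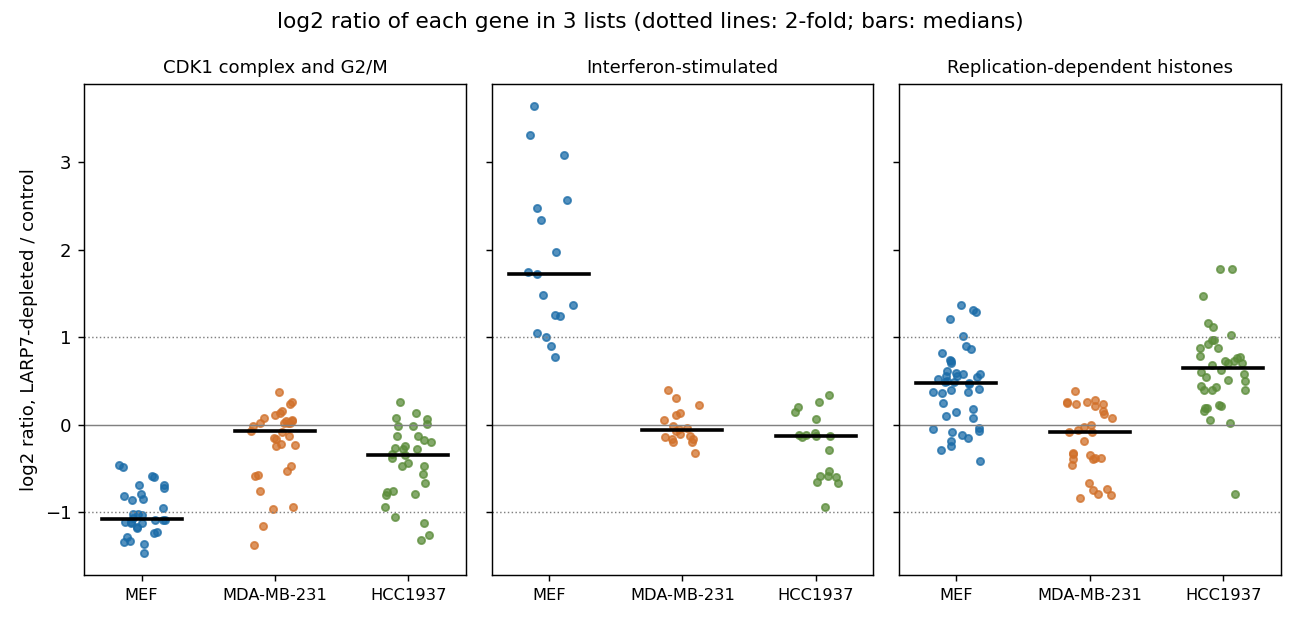
Each point is the log2 ratio of LARP7-depleted to control for 1 gene, in 3 gene lists and 3 cell types, with bars at list medians and dotted lines at 2-fold. The medians of the G2/M list were -1.07 in MEFs, -0.08 in MDA-MB-231 and -0.34 in HCC1937, and those of the interferon list 1.73, -0.06 and -0.13.

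In MDA-MB-231, siLARP7 was compared with siNC to ask what LARP7 restrains or sustains in a breast cancer line. Called protein-coding genes included the cyclin gene CCNB2 and a subunit of the protein translocon, and sterol genes stood low as a group. SEC61G, part of the channel that takes proteins into the endoplasmic reticulum, was at 36.9 RPKM with siNC and 10.7 RPKM with siLARP7 (log2 ratio -1.70), 28.9% of the control with an interval from 26.98 to 31.0%. CCNB2, a cyclin of CDK1, was at 20.3 and 7.20 RPKM (-1.38). Of 17575 genes tested, 88 were at least 2-fold higher and 130 at least 2-fold lower, but most of these were not mRNA genes: of 12885 protein-coding genes, 6 were higher and 27 lower.

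Around CDK1, the B-type cyclins, CDC25C and PLK1 were low, while other members stayed closer to their controls. CDC25C, the phosphatase that activates CDK1, was at 4.76 and 1.58 RPKM (log2 ratio -1.16). CCNB1 was at 50.3 and 25.4 RPKM (-0.96), 50.5% of the control with an interval from 48.5 to 52.7%, just short of the size rule. PLK1 was at 12.6 and 6.07 RPKM (-0.94) and CDK1 itself at 29.4 and 21.0 RPKM (-0.47, or -0.24 with the trend on GC content, length and level removed). The whole G2/M list had a median of -0.08 over 32 genes (percentile 11.5) with 2 called lower, since genes such as CDC20, at 42.8 and 47.7 RPKM, and AURKB, at 28.6 and 29.1 RPKM, were level. BRCA1 was at 4.91 and 5.08 RPKM, BRCA2 at 1.25 and 1.34 and BARD1 at 3.20 and 3.01 RPKM, and the homologous recombination list had a median of 0.02 (percentile 63.6), or 0.08 (percentile 98.0) with that trend removed.

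Cholesterol synthesis and uptake genes had a median log2 ratio of -0.44 over 21 genes (percentile 0) without a called member. The sterol methyl oxidase MSMO1 was at 34.0 and 18.1 RPKM (-0.88) and the squalene epoxidase SQLE at 11.7 and 6.40 RPKM (-0.78). NF-kB targets and cytokines had a median of -0.21 (percentile 1.74), with IL6 at 32.2 and 16.0 RPKM and ICAM1 at 64.8 and 41.8 RPKM, but this list stood at percentile 30.1 with the trend removed, 17.9 without a level minimum, 3.32 at a minimum of 5 RPKM and 2.95 at a pseudocount of 0.1. Immediate early genes stood high (median 0.31, percentile 99.98), with FOS at 5.50 and 9.99 RPKM and EGR1 at 8.01 and 12.4 RPKM, as did mitochondrially encoded mRNAs (median 0.39, percentile 100), with MT-ND1 at 1590 and 2390 RPKM. Interferon-stimulated genes had a median of -0.06 (percentile 21.8) and histone genes -0.08 (percentile 7.78). With the trend removed, histone genes had a median of -0.22 (percentile 0) over 26 of 31 members, but were at percentile 24.3 over the 17 matched by ID. HOX genes (-0.17, percentile 0.11) and senescence genes (-0.20, percentile 1.87) also stood low with the trend removed, and did not stand apart as deposited.

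Other protein-coding genes at least 2-fold lower were the gap junction gene GJA1, at 7.23 and 2.15 RPKM (-1.39), the cystatin CST1 at 52.9 and 20.1 RPKM (-1.35), the sclerostin gene SOST at 3.96 and 0.995 RPKM (-1.31) and CCDC151, which serves motile cilia, at 6.78 and 2.13 RPKM (-1.31). Those higher were MED18, a Mediator subunit, at 3.96 and 9.74 RPKM (1.12), C1orf233 at 4.003 and 9.15 RPKM (1.02), NPIPB15 at 3.02 and 8.42 RPKM (1.23), POTEJ (1.11), POTEE (1.05) and MT1H, a metallothionein, at 0.307 and 1.63 RPKM (1.01). NPIPB15, POTEE, POTEJ and MT1H have near-identical relatives that share reads, so their values are uncertain. With the trend removed C1orf233 was not called (0.79). The authors' deposited table lists 88 genes at a log2 change of at least 1 and 125 at -1 or less in this line.

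The same siRNA comparison in HCC1937 asks what LARP7 depletion does in a BRCA1-mutant background. BRCA1 RNA and mitotic genes were lower with siLARP7, and histone genes were higher. BRCA1 was at 3.29 RPKM with siNC and 0.785 RPKM with siLARP7 (log2 ratio -1.26, or -1.20 after scaling to a median ratio of 1), 23.9% of the control with an interval from 21.2 to 26.8%. The histone gene HIST2H2BE was at 5.49 and 16.9 RPKM (1.47), 308% of the control with an interval from 281 to 339%. Of 15797 genes tested, 63 were at least 2-fold higher and 195 at least 2-fold lower, and of 11953 protein-coding genes 25 were higher and 107 lower.

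Values in this line carry a shift and a trend. The median log2 ratio of genes above the level minimum in both libraries was -0.13, and scaling the libraries to a median ratio of 1 gave 116 genes higher and 128 lower, while a trimmed mean gave 144 and 113, so the share of called genes that were higher went from 24.4% to 47.5% and 56.0%. The log2 ratio also followed the GC content of transcripts across protein-coding genes (Spearman correlation 0.57), and removing a trend on GC content, length and level left 11 protein-coding genes higher and 52 lower. The fit left the shift in place, so these counts, and all ratios and calls of this line with the trend removed, still hold it. The excess of lower genes among them can therefore stem from the shift.

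**Figure D3:**
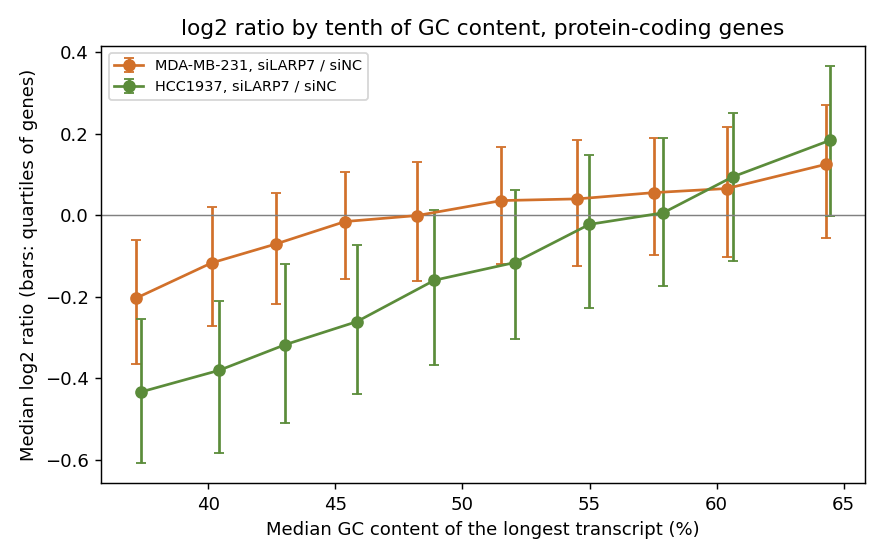
Median log2 ratio (points, with quartiles of genes as bars) of siLARP7 to siNC in 10 groups of protein-coding genes ordered by GC content of the longest transcript, against the median GC percent of each group. In HCC1937 the median went from -0.43 in the lowest group to 0.18 in the highest, and in MDA-MB-231 from -0.20 to 0.12.

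The CDK1 and G2/M list of HCC1937 had a median log2 ratio of -0.34 (percentile 0), or -0.23 after scaling to a median ratio of 1. As deposited, 4 of its 32 members were at least 2-fold lower: HMMR, which acts at the spindle, at 21.0 and 7.84 RPKM (-1.32), the kinetochore motor CENPE at 3.87 and 1.03 RPKM (-1.26), CENPF at 7.47 and 2.88 RPKM (-1.13) and KIF11 at 6.22 and 2.48 RPKM (-1.05). KIF11 was not called after that scaling (-0.95), and neither it nor CENPF (-0.98) was called with the trimmed mean. With the GC, length and level trend removed, HMMR alone of the 4 was called (-1.07), with CENPE at -0.89, CENPF at -0.85 and KIF11 at -0.74. These ratios still hold the downward shift of this line, and calls with both removed were not made. HMMR stood at percentile 0.23 of protein-coding genes. CDK1 was at 31.1 and 25.6 RPKM (-0.27, scaled -0.14) and CCNB1 at 41.0 and 31.4 RPKM (-0.38, scaled -0.25). With the trend removed these were -0.12 and -0.35, at percentiles 53.9 and 21.1 of protein-coding genes. DNA replication and G1/S genes had a median of -0.09 (percentile 26.1), which turned to 0.04 after scaling.

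Homologous recombination genes had a median of -0.43 (percentile 0.45), or -0.30 after scaling, and BRCA1 was the called member of 21. PALB2, which joins BRCA1 to BRCA2, was at 2.89 and 1.03 RPKM (-0.93), and BARD1 at 2.11 and 1.24 RPKM (-0.48, scaled -0.40, and -0.16 with the GC, length and level trend removed, at percentile 46.9 of protein-coding genes). BRCA2, at 0.856 and 0.193 RPKM, was below the level minimum, and the authors' deposited table lists log2 changes of -1.86 for BRCA1 and -1.80 for BRCA2. End joining genes had a median of -0.44 (percentile 1.46), with POLQ, the polymerase of microhomology-mediated joining, at 1.51 and 0.467 RPKM (-0.77) and RIF1 at 2.30 and 0.953 RPKM (-0.76). With the GC, length and level trend removed, neither list stood apart (percentiles 3.26 and 10.8), nor did La-related proteins (median -0.50, percentile 0.86 before and 4.57 after). BRCA1 then had a log2 ratio of -1.01, at percentile 0.42 of protein-coding genes. That ratio still holds the downward shift of this line, and whether BRCA1 would be called with both removed was not tested. Mesenchymal genes (median 0.16, percentile 99.8), ribosomal protein genes (-0.09, percentile 99.5) and cholesterol genes (-0.01, percentile 97.6) stood above random lists with the trend removed. As deposited they did not (percentiles 92.65, 6.015 and 95.76).

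Histone genes stood at a median of 0.65 over 38 genes (percentile 100), or 0.72 over 40 genes after scaling, with 6 members called as deposited, 9 after that scaling and 11 with the trimmed mean. With the trend removed the median was 0.43 over 34 genes (percentile 100). HIST1H2AE was at 3.63 and 9.35 RPKM (1.16, or 0.996 with the trend removed), and the near-identical HIST2H2AA3 (53.3 and 185 RPKM, 1.77) and HIST2H2AA4 (1.78) share reads, so their separate values are uncertain. Immediate early genes had a median of 0.35 (percentile 99.99), or 0.17 (percentile 100) with the trend removed, with the phosphatase DUSP1 called, at 14.3 and 31.0 RPKM (1.06, or 0.90 with the trend removed). Collagens and matrix genes had a median of 0.31 over 6 genes (percentile 99.8), but stood at percentile 95.8 with the trend removed. HOX genes had a median of 0.07 over 18 genes (percentile 99.6), or 0.15 after scaling. Mitochondrially encoded mRNAs were low, at a median of -0.49 (percentile 0), or -0.36 after scaling and -0.63 with the trend removed, with MT-CO3 at 730 and 437 RPKM (-0.74).

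Apart from histone genes, the protein-coding genes with the largest ratios in HCC1937 belonged to several processes. Higher were TMEM238, at 84.8 and 285 RPKM (1.73), the CDK inhibitor CDKN1C at 1.999 and 7.30 RPKM (1.47) and IER5L at 13.6 and 34.7 RPKM (1.29). Lower were the nuclear receptor interacting factor LRIF1, at 9.17 and 2.58 RPKM (-1.51), the arginyl-tRNA synthetase RARS at 20.1 and 6.46 RPKM (-1.50), ZNF28 at 4.50 and 1.04 RPKM (-1.43), the methyltransferase METTL18 at 7.01 and 2.07 RPKM (-1.39), MRFAP1L1 at 15.0 and 5.15 RPKM (-1.38) and TRMT10C, a subunit of mitochondrial RNase P, at 6.84 and 2.03 RPKM (-1.37). All of these were also called under both other scalings. TMEM238 (0.94) and IER5L (0.91) were not called with the trend removed, but those ratios still hold the downward shift of this line. The authors' deposited table lists 43 genes at a log2 change of at least 1 and 532 at -1 or less in this line.

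**Figure D4:**
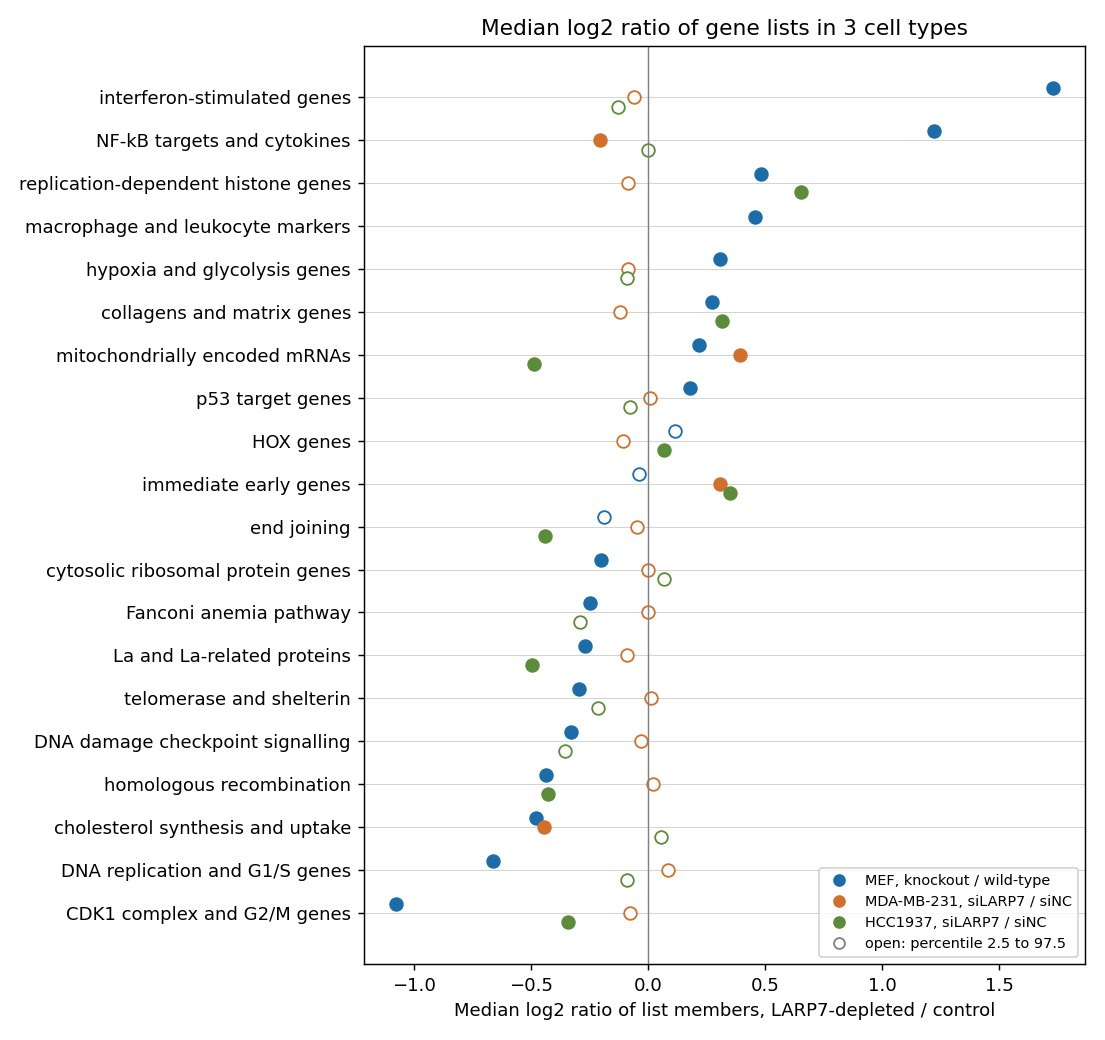
Median log2 ratio of LARP7-depleted to control for gene lists that stood apart in at least 1 cell type, with filled points where the list stood apart from random lists and open points elsewhere. Cholesterol genes stood low in MEFs (-0.48) and MDA-MB-231 (-0.44), and histone genes high in MEFs (0.48) and HCC1937 (0.65).

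Set side by side, the cell types shared few changed genes. Of 14245 genes tested in both human lines, 2 were at least 2-fold higher in both (MIR611 and AL356020.1) against 0.148 for independent lists, and 2 lower in both (MIR3158-1 and MIR4775) against 1.00, while 6 were called in opposite directions against 0.838. Of the 4 called the same way, 3 are microRNA genes and AL356020.1 has no type in the annotation, and MIR3158-1 rests on about 14 and 3 reads in MDA-MB-231 and 19 and 5 reads in HCC1937. MIR611 was listed at 0 in both controls, and with siLARP7 at 1.12 RPKM in MDA-MB-231 and 1.47 RPKM in HCC1937. MIR4775 was at 2.70 and 0.263 RPKM in HCC1937. No gene was called the same way in all 3 cell types, of 7791 tested by shared symbol. Across genes, which are not independent replicates, log2 ratios correlated with a Pearson's r of 0.06 (Spearman correlation 0.08) between the human lines over 14245 genes, -0.01 (-0.04) between MEFs and MDA-MB-231 and 0.21 (0.23) between MEFs and HCC1937. The correlation between the human lines turned with the trend: over 11130 protein-coding genes Pearson's r was 0.11 as deposited and -0.10 with the trend removed.

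MEFs and HCC1937 shared 8 lower genes of 8011 tested, against 0.665 for independent lists, of which KIF11, HMMR and CENPE belong to the G2/M list. The others were the cytokinesis gene ECT2, the proliferation marker MKI67, the condensin subunit SMC4, CKAP2L and the microRNA gene MIR15B. Under each of the other scalings 3 of the 8 were shared, HMMR, CENPE and CKAP2L, and with the trend removed in HCC1937 2 were, HMMR and MKI67, against 0.266. MEFs and MDA-MB-231 shared CCNB2 as a lower gene (-1.18 and -1.38), joined by PLK1 with the trend removed in MDA-MB-231, and the small nucleolar RNA SNORD88C as a higher one (1.11 and 1.40).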

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

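The results in this part differed in direction between cell types, each of which holds 1 library per condition, and none of the differences was tested. NF-kB targets and cytokines stood high in MEFs (median log2 ratio 1.22) and low in MDA-MB-231 (-0.21), so that MDA-MB-231 lay below MEFs by a difference of -1.43. In MDA-MB-231 this list did not stand apart with the trend on GC content, length and level removed (-0.05, percentile 30.1), nor at other level minimums or a pseudocount of 0.1. Mitochondrially encoded mRNAs stood low in HCC1937 (-0.49) and high in MDA-MB-231 (0.39) and MEFs (0.22), with differences of -0.88 and -0.71.

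Among single genes called in opposite directions in the human lines, the clone-named gene AL592188.7 was at 795 RPKM with siNC and 242 RPKM with siLARP7 in MDA-MB-231 and at 981 and 3106 RPKM in HCC1937, a difference of 3.38 between the log2 ratios. The mitochondrial serine tRNA gene MT-TS2 was at 106 and 440 RPKM in MDA-MB-231, about 310 and 1384 reads, and at 3.78 and 0.670 RPKM in HCC1937, about 11 and 2 reads, with a difference of -3.56. AC090340.1 was at 2.02 RPKM and listed at 0 in MDA-MB-231, and listed at 0 and at 1.32 RPKM in HCC1937, with a difference of 2.80. AL691523.1 was at 1.15 and 3.75 RPKM in MDA-MB-231 and at 1.45 RPKM and listed at 0 in HCC1937, with a difference of -2.43. The microRNA gene MIR4674 was read about 12 and 1 times in MDA-MB-231 and 0 and 5 times in HCC1937, with a difference of 2.73. Genes as short as tRNA and microRNA genes reach high RPKM from few reads.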

How the results depend on the processing

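The trend removal and the restriction to protein-coding genes were added after the data were seen, and the other settings were planned. Among counts, LARP7 ratios, numbers of lists apart, overlaps and correlations, 47 values stayed within their limits, 31 moved and 1 turned its direction. That is the correlation between the human lines, 0.06 over all tested genes, which was 0.11 over protein-coding genes and -0.10 over the same genes with the trend removed. Without the trend LARP7 ratios were -0.66 in MDA-MB-231 and -0.48 in HCC1937. With a pseudocount of 0.1, which by construction lets low genes reach 2-fold, 758 genes were higher and 276 lower in knockout MEFs, 308 and 340 in MDA-MB-231 and 208 and 903 in HCC1937, LARP7 ratios were -1.39, -0.92 and -0.94, and 20 genes went the same way in both human lines against 11.0 for independent lists. At a 1.5-fold threshold, which by construction adds genes, the counts were 1156 and 582 in MEFs, 507 and 708 in MDA-MB-231 and 435 and 1712 in HCC1937, with 94 genes the same way in both lines (63.7 for independent lists) and 3 in all 3 cell types (against 1.00): LARP7, CDC25C and the kinetochore gene NSL1. LARP7 was the gene depleted in each comparison, so its place among the 3 follows from the design. With a level minimum of 5 RPKM, which by construction drops low genes, 202 genes were higher in MEFs, 30 higher and 61 lower in MDA-MB-231, 110 lower in HCC1937, and 0 the same way in both lines (0.496 for independent lists). The same minimum left 4 lists apart in HCC1937, where 9 stood apart before: the end joining, matrix and HOX lists fell under 5 members, and for the La-related (percentile 3.53) and homologous recombination lists (8.79) the cause was not tested. HCC1937 scaled to a median ratio of 1 gave 116 higher and 128 lower, and scaled by the trimmed mean 144 and 113, so that higher genes came to outnumber lower ones, which follows from its shift. Having no level minimum is void for counts of calls, as a 2-fold call at a pseudocount of 1 already needs 1 RPKM. The alternative for read counts was not run, because the values are RPKM. No paired analysis was possible because the groups share only the number 1, given in accession order.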

Other observations

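The S phase, leukocyte, shared response and culture checks below were chosen after the results were seen, and the trend and shared read checks were set before they were run. The list of CDK inhibitors and senescence genes did not stand apart in knockout MEFs. It holds Lmnb1, which falls in senescent cells, beside CDK inhibitors, so its median cannot decide whether cells had left the cycle. Of 12 senescence genes, with a median log2 ratio of 0.14 (percentile 94.9), Igfbp3, a growth factor binding protein, was at least 2-fold higher, at 7.35 and 18.8 RPKM (1.25). Lmnb1, a lamin that falls in senescent cells, was at 24.5 and 12.3 RPKM (-0.94), the CDK inhibitor gene Cdkn2c at 10.3 and 4.67 RPKM (-0.99) and the p16 and ARF gene Cdkn2a at 28.0 and 39.9 RPKM (0.50), and with the trimmed mean scaling 1 member was called higher and 2 lower. The matrix protease Mmp9 was at least 2-fold higher, at 4.14 and 12.1 RPKM (1.35), as was the tight junction gene Cldn3, at 0.861 and 3.72 RPKM (1.34).

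Single HOX and neural genes differed between the MEF cultures. Of 34 HOX genes, 20 were above 0 and 14 below, with a median of 0.11 (percentile 94.9), and 1 was called. The posterior HOX gene Hoxc12 was at least 2-fold lower, at 2.58 and 0.676 RPKM (-1.09), with its neighbours Hoxc10 at 9.53 and 5.25 RPKM (-0.75) and Hoxc11 at 3.06 and 1.45 RPKM (-0.73), while Hoxb4 was at 3.69 and 7.34 RPKM (0.83). The neural stem cell factor Sox2 was at least 2-fold lower, at 3.24 and 0.730 RPKM (-1.29), and the glial gene S100b at least 2-fold higher, at 1.32 and 3.70 RPKM (1.02), which was not called with the trimmed mean (0.97). In HCC1937, siLARP7 came with at least 2-fold lower IL1A, a proinflammatory cytokine, at 19.9 and 8.93 RPKM (-1.07), which was not called after scaling to a median ratio of 1 (-0.95), with the trimmed mean (-0.90) or with the trend removed (-0.89).

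Interferon-stimulated genes in knockout MEFs could reflect leukocytes in the culture, a response to LARP7 loss or a difference between cultures. Leukocytes as the cells that carry these transcripts are argued against, as their markers gained 3.10% of the RPKM that interferon-stimulated genes gained. An indirect effect of few leukocytes on the fibroblasts was not tested. A response shared by all 3 cell types at the depletion reached here is argued against too. The highest percentile of the list in the human lines was 56.7. With 52.2% of LARP7 RNA left in MDA-MB-231 and 51.4% in HCC1937, these lines cannot decide whether fuller loss would raise these genes. A response of MEFs to LARP7 loss and a difference between 2 cultures unrelated to genotype cannot be told apart with 1 library per genotype.

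Histone genes were high in knockout MEFs and in HCC1937. More cells in S phase could raise them in MEFs, but DNA replication and G1/S genes had a median log2 ratio of -0.66 there. Reads shared within the HIST2 cluster are not the whole cause in MEFs. Without it the median went from 0.48 over 44 genes to 0.41 over 39 and the percentile stayed at 100. Sharing of reads among the other histone genes was not tested. The trend on GC content, transcript length and level is not the whole cause in HCC1937. Removing it took the median from 0.65 to 0.43 over the 34 of 38 members with a value, at percentile 100. Replication-dependent histone mRNAs lack a poly(A) tail, and a larger share of histone RNA with a tail was not tested.

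Cell cycle and repair genes of HCC1937 behaved differently once the trend on GC content, transcript length and level was removed. That trend could stem from library preparation or from the treatment. For G2/M genes the median went from -0.34 to -0.36, with 95% of random lists at -0.15 to 0.12 before and -0.25 to -0.06 after, and the percentile of 0 after removal argues against the trend as the whole cause. For homologous recombination genes the median went from -0.43, with random lists at -0.36 to 0.01, to -0.28, with random lists at -0.29 to -0.0047, and the percentile went from 0.45 to 3.255. That call ended as the median moved towards the random lists by more than their lower limit did, which fits the trend as a cause. Random lists after removal held protein-coding genes only, and the trend included level, so GC content and length cannot be singled out as the cause. The list was not tested without BRCA1.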
